A study of Mus musculus with 12 samples.

How the data were processed

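Messenger RNA was sequenced from mouse B-cell acute lymphoblastic leukaemia (B-ALL) cells of 2 genotypes, each cultured for 24 h in regular or low-glucose medium. The 12 libraries form 4 groups of 3: DKO cells (Bax and Bak1 deleted) and TKO cells (Bax, Bak1 and Mcl1 deleted) in each of the 2 media. Per the labels, total RNA was purified on silica columns, and strand-specific libraries were made with a Kapa mRNA HyperPrep kit. The labels name no second line of either genotype, so genotype and cell line cannot be separated. They do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

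The authors aligned the reads to mm10 with STAR 2.7.3a and used DESeq2 1.22.1, per the submitters' processing notes. The deposited count table holds whole-number counts of reads per gene for 24982 gene symbols, not normalized. The deposited TPM table holds TPM, a length-scaled abundance, for 23640 symbols, and each library's TPM sum to 1000000. The authors also deposited a table of DESeq2 results for TKO against DKO in each medium, and per the file headers these hold a normalized mean expression, which is a score with no fixed range, a log2 fold change with its standard error on the log2 scale, a test statistic (also a score) and p-values, raw and adjusted. The strand setting used in counting is not given, so overlapping and antisense genes cannot be told apart here. The treatment of reads shared by paralogs is not given either. No row of the count table lacked a gene name. Symbols were matched to the mouse annotation of GRCm38, the assembly also called mm10, for coordinates, GC content and length (24853 symbols matched).

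The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with the group (count minimum 10, total minimum 15), which left 11988 genes. Libraries were scaled with TMM, and 1 quasi-likelihood model with a mean for each of the 4 groups was fitted to all 12 libraries (8 residual degrees of freedom). F-tests were made for TKO against DKO in each medium, for low glucose against regular medium in each line, and for the interaction. The interaction is the TKO response to low glucose minus the DKO response, on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM (counts scaled to 1000000 per library, with TMM factors), as mean ± SD of 3 libraries, and log2 fold changes are given ± SE from the model. Where the lower group had no counts, the fold is a lower bound from 3 counts over that group. Where the lower group had 1 to 3 counts, the ratio is given with its 95% counting interval. Bounds and intervals cover counting error only.

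Gene lists were fixed from textbook pathway membership before the data were examined, as were the comparisons, the tests and the alternatives other than those named last below. They cover the BCL-2 family, mitochondrial fatty acid oxidation, peroxisomal fatty acid oxidation, fatty acid uptake, storage and lipolysis, fatty acid synthesis, cholesterol synthesis and uptake, glycolysis and lactate, the TCA cycle and pyruvate entry, nuclear respiratory chain subunits, mitochondrially encoded transcripts, and mitochondrial dynamics and cristae. They also cover ATF4 targets of the integrated stress response, the unfolded protein response of the endoplasmic reticulum, p53 targets, the cell cycle, MYC and ribosome biogenesis, pentose phosphate and nucleotide synthesis, NRF2 targets, lysosome and autophagy, HIF targets, the interferon response, FOXO and glucose-sensing genes, early B-cell identity, and markers of T, myeloid, erythroid or megakaryocytic, and stromal cells. Each list with at least 5 tested members was tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the lists within each comparison. Camera asks whether a list moved relative to the other genes. It was repeated with an estimated correlation, and with fry, which asks whether the members of a list moved one way on balance and makes no comparison with other genes.

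Named genes follow a rule fixed with the lists. Mcl1, Bax and Bak1 come first. In each pairwise comparison the rule takes the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM over all libraries and no overlap between the 3 and 3 libraries, and in the interaction the 4 largest each way. Predicted genes, Riken clones and pseudogenes are left out. From each list it takes up to 4 members per comparison with the lowest adjusted p, further called members where a list is described in full, and uncalled members, given as values, where a list's result rests on them.

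The test was tried on simulated data. Changes of 1.25-, 1.5-, 2- and 4-fold were planted in simulated counts with the depths of these libraries and 1 spread per gene. Each size was planted in 48 to 50 genes, among 11827 or 11838 tested. The real comparisons called 29.6% to 74.6% of genes, and the cutoff depends on that share. The simulated shares therefore do not carry over to the real comparisons. For TKO against DKO in regular medium 55.1%, 85.7%, 94% and 100% of the planted genes were called, and 5.1% of the calls were false. For low glucose in TKO the shares were 45.8%, 81.6%, 94% and 100%, with 5.4% false. The common biological coefficient of variation in the real libraries was 5.4%.

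Alternatives were DESeq2's size factors or library size alone for scaling, no filter or a mean of at least 1 CPM, DESeq2 1.42.0, limma on log2(TPM + 1), the compared groups alone, the replicate number as a block, leaving out each library, a 2-fold threshold and leaving out the 20 most abundant genes. Added after the data were seen were leaving out the ribosomal RNA precursor Rn45s, leaving out both TKO libraries numbered 2, and leaving Mcl1, Bax and Bak1 out of the BCL-2 list. All 12 libraries were used, and no library was left out of the main results.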

Results

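Gene expression was measured in 12 libraries of mouse B-ALL cells, 3 for each combination of line (DKO or TKO) and medium (regular or low glucose, 24 h). The title of the series concerns MCL-1 and a dependence on fatty acid oxidation. The comparison of the lines asks which transcripts differed between the TKO line, with Mcl1 deleted, and the DKO line. Both lack Bax and Bak1, the genes of the pore-forming effectors of mitochondrial apoptosis. Deletion of Mcl1 cannot be separated there from other differences between the lines. The comparison of media asks how each line responded when glucose was limited. Total gene counts ran from 45914440 to 56260867 per library in DKO in regular medium and from 35758895 to 46925274 in DKO in low glucose. They ran from 25908668 to 30874107 in TKO in regular medium and from 22190736 to 42140396 in TKO in low glucose. The ribosomal RNA precursor Rn45s took 1.99% to 4.62% of the counts. The first principal component of log2 CPM held 88.3% of the variance and separated the lines, and the second held 6.7% and separated the media. TKO libraries lay further from their group means than DKO libraries did, most of all replicate 2 in each medium and replicate 3 in low glucose (median absolute log2 deviation of genes above 100 CPM of 0.069, 0.075 and 0.072, against 0.033 to 0.04 in the remaining TKO libraries).

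Mcl1, which encodes an anti-apoptotic member of the BCL-2 family (mm10 chromosome 3, 95656944 to 95663179), stood at 239 ± 2.51 CPM in DKO and 0.406 ± 0.0619 CPM in TKO in regular medium (SD, n = 3). In low glucose it stood at 270 ± 3.59 CPM in DKO and 0.255 ± 0.0791 CPM in TKO. It was thus 580-fold lower in TKO in regular medium (log2 -9.18 ± 0.166) and 1050-fold lower in low glucose (log2 -10.04 ± 0.188), with adjusted p of 1.79e-17 and 5.28e-18. The highest TKO library reached 0.187% of the DKO mean over both media. Bax (chromosome 7, 45461695 to 45466903) and Bak1 (chromosome 17, 27019812 to 27028627), both deleted in each line per the labels, kept transcripts in each line and were lower in TKO. In regular medium Bax stood at 17.1 ± 0.175 CPM in DKO and 6.17 ± 0.259 CPM in TKO, 2.78-fold lower, and Bak1 at 16.9 ± 1.40 and 5.30 ± 0.713 CPM, 3.16-fold lower. In low glucose the differences were 3.24-fold for Bax and 4.02-fold for Bak1. No library without these deletions is in the series, so the deletions of Bax and Bak1 have no intact reference here.

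**Figure D1:**
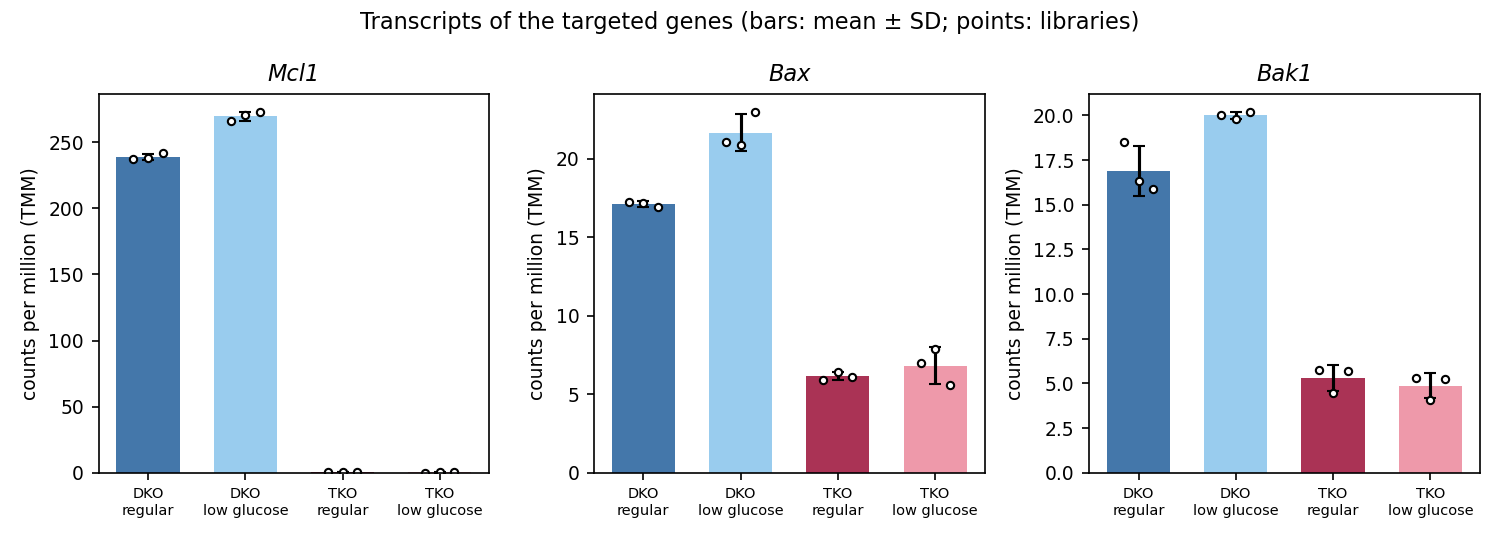
CPM of Mcl1, Bax and Bak1 in each library, by line and medium, with points for libraries and bars for mean ± SD. Mcl1 was at 239 CPM in DKO and 0.406 CPM in TKO in regular medium.

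In regular medium the lines differed in many lipid genes, with directions that varied within pathways. Cd36, which encodes a fatty acid translocase of the plasma membrane, was 20.5-fold higher in TKO (136 ± 4.35 against 6.66 ± 0.714 CPM, adjusted p = 2.49e-15). Cpt1a, the enzyme that commits long-chain fatty acids to mitochondrial oxidation, was 2.32-fold lower in TKO (44.9 ± 0.646 against 104 ± 1.65 CPM, log2 -1.22 ± 0.0356, adjusted p = 6.31e-13). The acyl-CoA dehydrogenases Acadsb and Acadm and the carnitine carrier Slc25a20 were 2.50-, 2.16- and 2.34-fold lower. Decr1, which encodes a reductase for unsaturated fatty acids, had no counts in any DKO library and 6.68 ± 0.671 CPM in TKO, at least 328-fold higher. Of the 27 tested genes of mitochondrial fatty acid oxidation 5 were higher in TKO, 17 were lower and 5 passed neither way, with the same counts adjusted over the list alone. The list as a whole was not called (median log2 -0.21, adjusted p = 0.426). Its mean was 0.12, opposite in sign to the median and the test, and rested on Decr1, with the median unchanged when Decr1 stood at its bound. In low glucose 8 members were higher and 13 lower (15 lower adjusted over the list alone), and the list again was not called (median -0.24, mean 0.22, adjusted p = 0.63). Cpt1a was then 2.13-fold, Acadsb 2.29-fold and Acadm 2.25-fold lower, Cd36 11.1-fold higher and Decr1 at least 406-fold higher.

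Other lipid lists were not called between the lines either. Of 15 peroxisomal oxidation genes 11 were lower and 2 higher in TKO in regular medium, with the same counts adjusted over the list alone (median -0.42, adjusted p = 0.213). Among them Acox3, an acyl-CoA oxidase gene, was 2.60-fold lower. In low glucose 10 were lower and 4 higher over all genes and adjusted over the list alone (adjusted p = 0.165). Of 18 genes of fatty acid uptake, storage and lipolysis 5 were higher and 8 lower in regular medium, over all genes and adjusted over the list alone (adjusted p = 0.947), among them the monoglyceride lipase Mgll, 4.63-fold lower, and the lipid-droplet coat gene Plin2, 1.86-fold lower. The median of that list was -0.07 and its mean 0.08. Of 16 fatty acid synthesis genes 9 were higher and 5 lower, with the same counts adjusted over the list alone (median 0.19, mean -0.63, test direction down, adjusted p = 0.63). The elongase Elovl7 was 62.5-fold and the acetyl-CoA synthetase Acss2 12.2-fold lower, while Elovl6 was 1.29-fold higher. Of 24 cholesterol genes 14 were higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 0.426).

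The lists called in regular medium all stood lower in TKO. Here and in the other comparisons, list calls given with no p for an estimated correlation held with it. Of 20 genes of the unfolded protein response of the endoplasmic reticulum, which fold and dispose of secretory proteins, 18 were lower and 0 higher, also adjusted over the list alone (median -0.50, adjusted p = 0.000148, and adjusted p = 0.0258 with an estimated correlation). The transcription factor gene Xbp1 was 7.59-fold lower (47.5 ± 2.43 against 361 ± 1.77 CPM), and the chaperone genes Pdia4 and Hyou1 were 2.94- and 1.62-fold lower. Of 28 interferon response genes 23 were lower and 4 higher, also adjusted over the list alone (median -0.70, adjusted p = 0.00337, and adjusted p = 0.261 with an estimated correlation). Ifi44, Ifih1 and Mx1 were 16.9-, 3.79- and 2.72-fold lower, while Ifi27l2a was 4.24-fold higher. Of 13 BCL-2 family genes 7 were lower and 3 higher, also adjusted over the list alone (adjusted p = 0.0383, and adjusted p = 0.489 with an estimated correlation). That call ended without Mcl1, Bax and Bak1 (adjusted p = 0.963) and without TKO replicate 2 in regular medium (adjusted p = 0.0745). Bcl2l11, which encodes the pro-apoptotic BIM, was 1.84-fold higher, and Bbc3, which encodes PUMA, was 1.68-fold lower.

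Lists of cell type and metabolism held large single-gene differences in both directions. Of 30 early B-cell genes 14 were higher in TKO and 12 lower (15 and 12 adjusted over the list alone, adjusted p = 0.426). Dntt, which encodes the template-independent polymerase of V(D)J joining, was 16.8-fold lower (23.8 ± 0.412 against 400 ± 8.42 CPM), and Ikzf3, a lymphoid transcription factor gene, was 174-fold higher (193 ± 19.4 against 1.09 ± 0.249 CPM). Of 21 glycolysis genes 13 were higher and 2 lower, with the same counts adjusted over the list alone (median 0.19, mean -0.07, test direction up, adjusted p = 0.576). Those lower were the hexokinase gene Hk1, 14.3-fold, and the lactate dehydrogenase gene Ldhb, at least 24.8-fold. Of 35 ATF4 targets 17 were higher and 5 lower (the same adjusted over the list alone, adjusted p = 0.222), with the serine synthesis gene Psat1 2.18-fold and the transsulfuration gene Cth 7.09-fold higher. Of 21 p53 targets 8 were higher and 11 lower, also adjusted over the list alone (median -0.22, mean 0.66, test direction up, adjusted p = 0.738). The cell cycle inhibitor gene Cdkn1a was 2.02-fold lower and Phlda3 134-fold higher. Of 34 cell cycle genes 23 were higher and 1 lower (25 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.119).

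Outside the lists, some genes had transcripts in 1 line and none in the other. Among the genes in TKO without counts in DKO in regular medium were the kinesin gene Kif16b (54.3 ± 4.82 CPM, at least 2670-fold higher), Bhlhb9, the small GTPase gene Arl4c, the focal adhesion kinase gene Ptk2, Zfp827 and the phosphorylase kinase subunit gene Phka1, the last at least 1340-fold higher. Among the genes without counts in TKO in regular medium were Uaca (136 ± 2.99 CPM in DKO, at least 3890-fold lower in TKO), the organic anion transporter gene Slco1a5, Fndc3b, the scramblase gene Plscr2 and the galactosyltransferase gene B3galt5, the last at least 1090-fold lower. Counts of Slco1a5 and Plscr2 may include reads of close paralogs. In all, 7395 of 11988 genes were called, 3396 higher and 3999 lower in TKO, and 991 and 1139 of these differed at least 2-fold. That balance turned with DESeq2's size factors, to 3935 higher and 3524 lower. By chromosome, a grouping made after the values were seen, genes of chromosome 18 stood higher in TKO (median log2 0.52 over 238 genes in regular medium, 0.60 in low glucose), and the medians of the other 18 autosomes lay between -0.06 and 0.00 in regular medium. The Y-linked genes Uty, Eif2s3y, Kdm5d and Ddx3y held 13790 to 45038 counts over the 6 DKO libraries and 7 to 30 counts over the 6 TKO libraries.

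**Figure D2:**
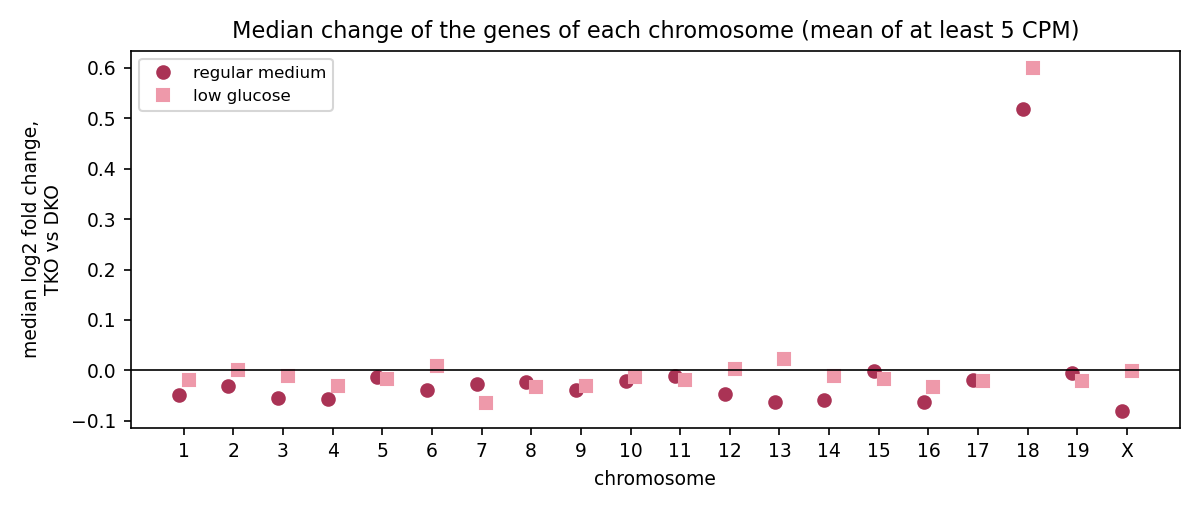
Median log2 fold change, TKO against DKO, of the genes of each chromosome with a mean of at least 5 CPM, in both media, without the Y chromosome. Chromosome 18 stands at 0.52 in regular medium and 0.60 in low glucose.

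In low glucose the list with the lowest p was the cell cycle, all 34 genes of which were higher in TKO, also adjusted over the list alone (median 0.99, adjusted p = 1.4e-14, and adjusted p = 0.00803 with an estimated correlation). The mitotic checkpoint kinase gene Bub1 stood at 202 ± 11.6 CPM in TKO and 73.6 ± 1.89 CPM in DKO, 2.74-fold higher, and Uhrf1, Ccna2 and Cdc6 were 2.76-, 2.36- and 2.25-fold higher. All 20 unfolded protein response genes were lower in TKO, also adjusted over the list alone (median -0.70, adjusted p = 1.56e-06, and adjusted p = 0.0118 with an estimated correlation), with Xbp1 8.24-fold, Derl3 20.6-fold and Pdia4 3.5-fold lower. Of 29 lysosome and autophagy genes 22 were lower and 4 higher, also adjusted over the list alone (median -0.65, adjusted p = 0.00991, and adjusted p = 0.231 with an estimated correlation), with the protease genes Ctsb and Ctsd 4.03- and 2.23-fold and the autophagy receptor gene Sqstm1 2.55-fold lower. Of 28 interferon genes 23 were lower and 4 higher, also adjusted over the list alone (median -1.10, adjusted p = 2.66e-05, and adjusted p = 0.231 with an estimated correlation).

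Glycolysis genes stood higher in TKO in low glucose, with 17 of 21 higher and 2 lower, also adjusted over the list alone (median 0.38, adjusted p = 0.0252, and adjusted p = 0.281 with an estimated correlation). Ldha and Tpi1 were 1.75- and 1.71-fold higher, and the lactate exporter gene Slc16a3 stood at 11.6 ± 1.45 CPM in TKO against 0.602 ± 0.0883 CPM in DKO, 19.2-fold higher. Of 28 genes of MYC and ribosome biogenesis 26 were higher and 1 lower, also adjusted over the list alone (median 0.41, adjusted p = 0.0121, and adjusted p = 0.281 with an estimated correlation). Of 13 BCL-2 family genes 8 were lower and 4 higher, also adjusted over the list alone (adjusted p = 0.00451, and adjusted p = 0.281 with an estimated correlation). Without Mcl1, Bax and Bak1 that call ended (adjusted p = 0.675). Of 35 ATF4 targets 21 were lower and 9 higher, also adjusted over the list alone, and the list was not called (median -0.24, mean 0.63, test direction down, adjusted p = 0.63). Psat1 was 4.03-fold higher, against Trib3, Slc6a9, Atf3 and Sesn2, which were 2.39-, 2.65-, 2.59- and 2.22-fold lower. Of 18 HIF targets 9 were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.39), with Bnip3 3.58-fold higher and Egln3 at least 147-fold lower.

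Among the largest single differences in low glucose, among genes with a mean of at least 5 CPM over all libraries, the spectrin gene Sptbn1 stood at 326 ± 18 CPM in TKO and 0.0275 ± 0.031 CPM in DKO (log2 13.25 ± 0.737, adjusted p = 7.06e-17). Ptk2, the calcium sensor gene Ncs1, Xk, Marcks and Fpgt had no counts in DKO and were at least 791-fold higher in TKO. Slco1a5, Fndc3b, Plscr2, the GTPase gene Rab39b and Bex3 had no counts in TKO in low glucose and were at least 906-fold lower. In all, 8941 genes were called, 4462 higher and 4479 lower in TKO, and 1188 and 1259 of these differed at least 2-fold. The difference between the lines correlated across genes between the media (Pearson r = 0.965 over 11988 genes, which are not independent replicates). Of the called genes 2880 were higher in both media, where independent lists would share 1264, 3350 were lower in both (1494.1 for independent lists), and 219 went opposite ways. The 2 comparisons share no library.

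In DKO, low glucose raised ATF4 targets, genes of amino acid supply and stress signalling, more than any other tested list by the median. Of 35 members 27 rose and 1 fell, also adjusted over the list alone (median 0.91, adjusted p = 2.33e-31). The pseudokinase gene Trib3 rose from 2.80 ± 0.139 to 43.9 ± 0.234 CPM, 15.6-fold, and the glutathione-degrading enzyme gene Chac1, the glycine transporter gene Slc6a9 and Atf5 rose 10.5-, 10.3- and 8.16-fold. Psat1 alone fell (log2 -0.82). Of 16 NRF2 targets, which handle oxidative stress, 13 rose and 3 fell, also adjusted over the list alone (median 0.72, adjusted p = 1.33e-09), with Srxn1 up 13.3-fold and Hmox1 up 6.45-fold. Of 18 FOXO and glucose-sensing genes 14 rose and 1 fell, also adjusted over the list alone (median 0.60, adjusted p = 9.04e-10), with S1pr1 up 5.05-fold and Gadd45a up 4.41-fold. Of 29 lysosome and autophagy genes 22 rose and 2 fell (23 and 2 adjusted over the list alone, median 0.63, adjusted p = 5.52e-09), and Sqstm1 rose 2.31-fold. Of 18 HIF targets 12 rose and 1 fell, also adjusted over the list alone (median 0.43, adjusted p = 4.11e-05), with P4ha1 and Bnip3 up 2.19- and 2.37-fold. Interferon genes (18 of 28 up, 5 down, adjusted p = 0.000431) and unfolded protein response genes (12 of 20 up, 1 down, adjusted p = 0.0154) were also called, each with the same counts adjusted over the list alone.

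Growth genes fell in DKO in low glucose. All 34 cell cycle genes fell, also adjusted over the list alone (median -1.03, adjusted p = 4.87e-46), among them the replicative helicase gene Mcm7 (from 461 ± 4.38 to 188 ± 1.57 CPM, 2.46-fold lower) and the ribonucleotide reductase gene Rrm1 (2.02-fold lower). All 28 genes of MYC and ribosome biogenesis fell, also adjusted over the list alone (median -0.64, adjusted p = 8.1e-15), Nop58 by 1.82-fold. Of 19 pentose phosphate and nucleotide synthesis genes 14 fell and 3 rose, also adjusted over the list alone (median -0.61, adjusted p = 6.71e-07), and Ppat, which starts purine synthesis, was 1.90-fold lower. Of 26 TCA cycle genes 21 fell and 0 rose, also adjusted over the list alone (median -0.35, adjusted p = 9.44e-05), and Idh3a was 1.70-fold lower. Of 54 respiratory chain genes 44 fell and 2 rose (45 and 2 adjusted over the list alone, median -0.36, adjusted p = 9.12e-06, and adjusted p = 0.182 with an estimated correlation). Of 23 genes of mitochondrial dynamics 14 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.189 with an estimated correlation), with Nrf1 1.64-fold lower. Of 13 BCL-2 family genes 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00426, and adjusted p = 0.189 with an estimated correlation), with Bmf, a pro-apoptotic member, up 3.63-fold.

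Mitochondrial fatty acid oxidation was not called in DKO in low glucose, with 6 of 27 genes up and 10 down, also adjusted over the list alone (median 0.00, adjusted p = 0.612). Cpt1a and Acadsb rose 1.41- and 1.47-fold, and Acad9 and Acsl5 were 1.44- and 1.43-fold lower. Glycolysis was not called either, with 8 of 21 up and 8 down, also adjusted over the list alone (adjusted p = 0.345), Pfkp and Aldoa rising 1.67- and 1.68-fold, Slc16a3 rising 44.4-fold from 2 counts in regular medium (95% counting interval 12.3 to 367) and Ldha falling 1.29-fold. By the rule for named genes, called with a mean of at least 5 CPM over all libraries and no overlap between the groups, the 6 largest rises were those of the secretory protein gene Crisp3 (log2 4.0 ± 0.20), Trib3 (3.97), the stress-response gene Nupr1 (3.78), Chac1 (3.4), Cth (3.39) and Slc6a9 (3.36). By the same rule the 6 largest falls were those of the imprinted RNA gene H19 (-1.69 ± 0.0585), the linker histone genes Hist1h1b (-1.66) and Hist1h1e (-1.33), whose transcripts mostly lack the poly(A) tail that mRNA kits capture, the uracil glycosylase gene Ung (-1.63), Rsph1 (-1.35) and Mcm7 (-1.30). In all, 7512 genes were called, 3789 up and 3723 down, of which 519 rose and 173 fell at least 2-fold. With the compared groups alone 8711 were called.

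In TKO, low glucose also raised ATF4 targets. Of 35 members 29 rose and 1 fell (31 and 1 adjusted over the list alone, median 0.60, adjusted p = 2.01e-38), with Trib3 up 6.20-fold from 2.94 ± 0.403 to 18.3 ± 0.853 CPM and Chac1, Slc6a9 and Atf5 up 4.76-, 4.13- and 3.12-fold. Of 18 HIF targets 14 rose and 0 fell, also adjusted over the list alone (median 0.60, adjusted p = 9.16e-27), with Ndrg1 and Bnip3 up 3.09- and 2.20-fold. Of 21 glycolysis genes 13 rose and 1 fell, also adjusted over the list alone (median 0.41, adjusted p = 3.05e-14), with Slc16a3 up 35.3-fold, without a called interaction (adjusted p = 0.856), and Aldoa and Tpi1 up 1.70- and 1.55-fold. NRF2 targets (12 of 16 up, 1 down, the same adjusted over the list alone, adjusted p = 1.03e-13), lysosome and autophagy genes (18 of 29 up, 0 down, with 20 up adjusted over the list alone, adjusted p = 1.88e-05) and FOXO targets (9 of 18 up, 2 down, with 10 and 2 adjusted over the list alone, adjusted p = 3.81e-06) were called upward. BCL-2 family genes were called upward as well, with 7 of 13 up and 1 down, also adjusted over the list alone (adjusted p = 0.0183, and adjusted p = 0.243 with an estimated correlation), Bmf rising 2.23-fold. That call ended without TKO replicate 2 in regular medium (adjusted p = 0.0657).

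Growth and biosynthesis genes fell in TKO by less than 1.5-fold at the median. Of 34 cell cycle genes 23 fell and 0 rose (24 and 0 adjusted over the list alone, median -0.22, adjusted p = 8.4e-10), with Mcm7 1.43-fold lower. Of 28 genes of MYC and ribosome biogenesis 26 fell and 0 rose (27 and 0 adjusted over the list alone, median -0.29, adjusted p = 4.62e-14). Of 24 cholesterol genes 16 fell and 0 rose, also adjusted over the list alone (median -0.25, adjusted p = 1.2e-07). Pentose phosphate and nucleotide synthesis genes (14 of 19 down, 1 up, the same adjusted over the list alone, adjusted p = 1.59e-06) and TCA cycle genes (14 of 26 down, 3 up, with 17 and 4 adjusted over the list alone, adjusted p = 0.00355) were called downward. Respiratory chain genes (41 of 54 down, 0 up, with 43 and 0 adjusted over the list alone, adjusted p = 3.06e-11, and adjusted p = 0.0581 with an estimated correlation), mitochondrial dynamics genes (7 of 23 down, 1 up, the same adjusted over the list alone, adjusted p = 0.00325, and adjusted p = 0.103 with an estimated correlation) and fatty acid synthesis genes (6 of 16 down, 1 up, the same adjusted over the list alone, adjusted p = 0.0165, and adjusted p = 0.0593 with an estimated correlation) were called downward with the preset correlation alone.

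Mitochondrial fatty acid oxidation was not called in TKO in low glucose, with 8 of 27 genes up and 4 down, also adjusted over the list alone (median 0.04, adjusted p = 0.408), although Cpt1a and Acadsb rose 1.53- and 1.61-fold. By the rule for named genes, called with a mean of at least 5 CPM over all libraries and no overlap between the groups, which leaves out Slc16a3, the largest rises were those of the prostacyclin receptor gene Ptgir (log2 2.86 ± 0.0444), Trib3 (2.63), Nupr1 (2.56), Chac1 (2.25) and Lrp4 (2.20), and Cd28, a costimulatory receptor gene, went from 0 to 0.252 ± 0.141 CPM, at least 7.18-fold higher. By the same rule the largest falls were those of Pdzd2 (-1.58 ± 0.579, adjusted p = 0.0349), the small nucleolar RNA host genes Snhg3 (-0.85) and Snhg4 (-0.71), Ung (-0.79), the surface antigen gene Ly6a (-0.73) and the recombinase gene Rag1 (-0.73). Cd28, Lrp4 and Pdzd2 stood under 1 CPM in TKO. Cd28 and Lrp4 lost their calls in limma on log2(TPM + 1), and Pdzd2 lost its call in DESeq2, without replicate 2 or replicate 3 of TKO in either medium, and without both TKO libraries numbered 2. In all, 4781 genes were called, 2632 up and 2149 down, of which 317 rose and 32 fell at least 2-fold. With the compared groups alone 3298 were called, 1743 of them up, and with no filter 48.1% of the called genes rose, against 55.1%.

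**Figure D3:**
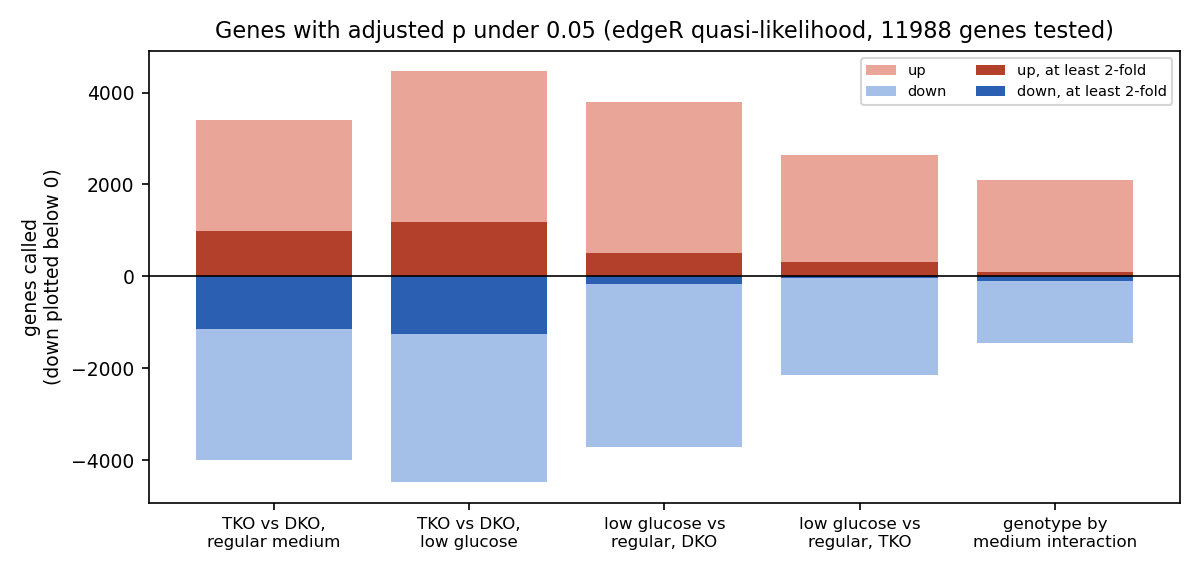
Genes called at an adjusted p under 0.05 in each comparison, with falls plotted below 0 and changes of at least 2-fold in darker bars. The media comparison called 7512 genes in DKO and 4781 in TKO, and 8711 and 3298 with the compared groups alone.

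**Figure D4:**
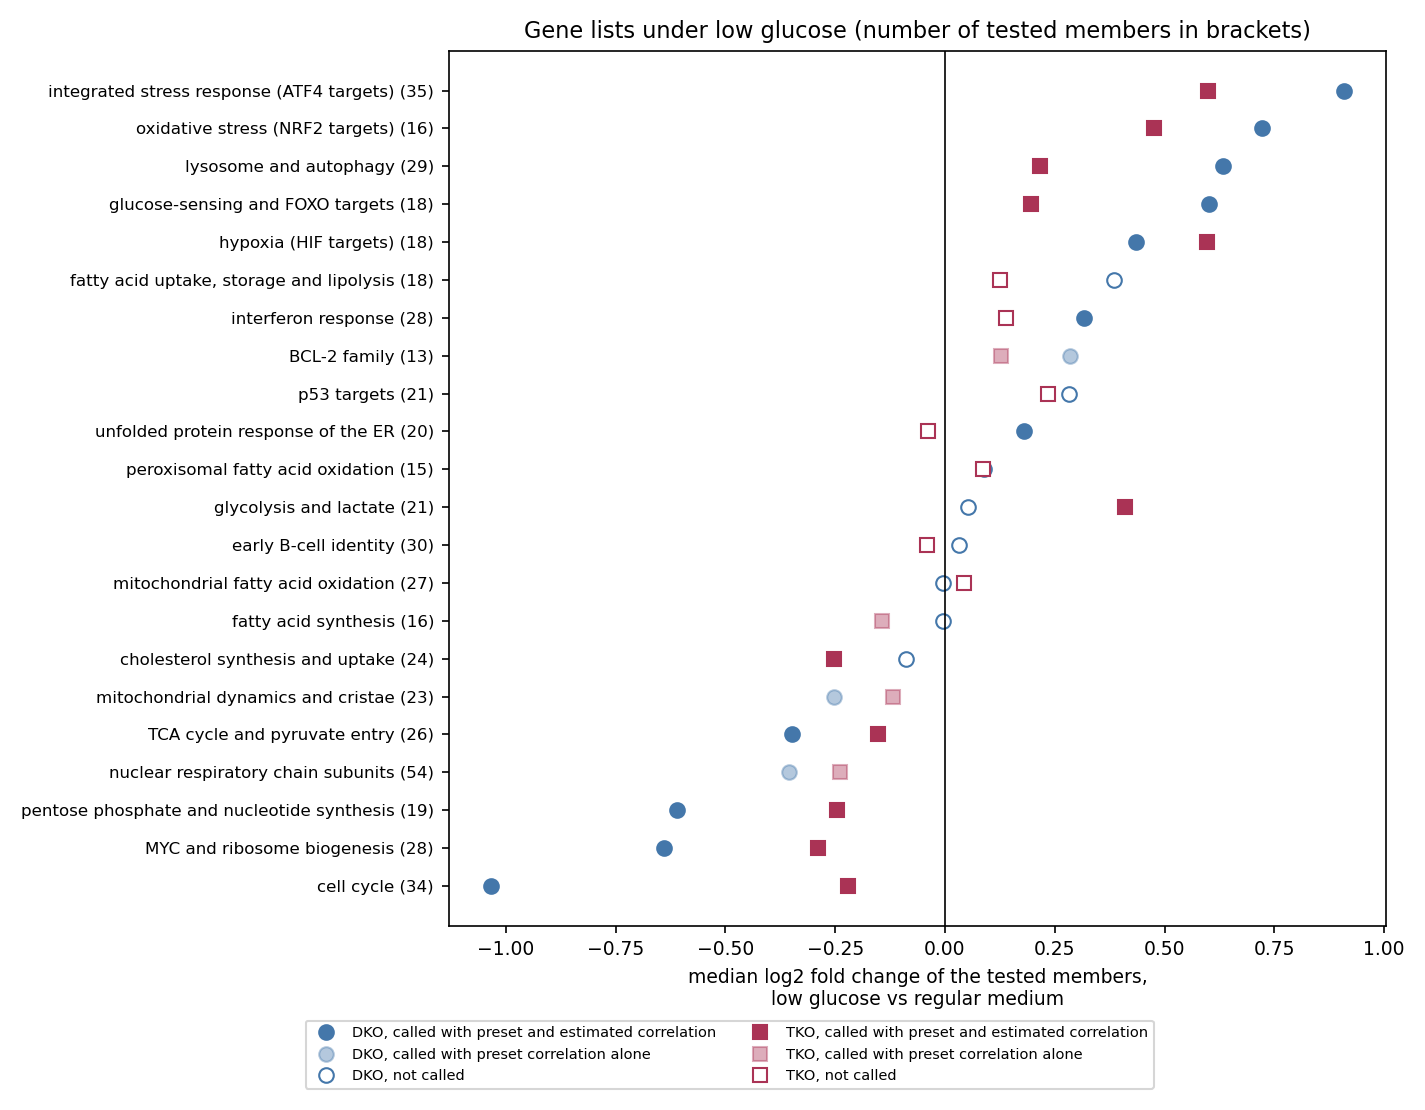
Median log2 fold change of each gene list in low glucose against regular medium, in DKO (circles) and TKO (squares), filled by whether camera called the list. Cell cycle genes stood at -1.03 in DKO and -0.22 in TKO.

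The interaction asks directly where the TKO response to low glucose differed from the DKO response. All 34 cell cycle genes had a positive interaction, also adjusted over the list alone (median 0.84, adjusted p = 2.7e-67), with Ccna2 and Bub1 both at 1.02 on the log2 scale. Of 28 genes of MYC and ribosome biogenesis 22 had a positive and 0 a negative interaction (25 and 0 adjusted over the list alone, median 0.36, adjusted p = 6.39e-08) with Nop58 at 0.59. Of 26 TCA cycle genes 14 were positive and 0 negative (15 and 0 adjusted over the list alone, adjusted p = 0.00101), with Pdk1, which restrains pyruvate entry, at 0.48. Of 35 ATF4 targets 22 rose less in TKO (23 adjusted over the list alone, median -0.32, adjusted p = 1.38e-11), among them Atf5 (-1.39 ± 0.0986), Slc6a9 (-1.32 ± 0.11) and Cth (-1.76 ± 0.151), while Psat1 had a positive interaction (0.89 ± 0.0495). Lysosome and autophagy genes (17 of 29 negative, 0 positive, the same adjusted over the list alone, adjusted p = 3.52e-07), FOXO targets (10 of 18 negative, 0 positive, with 12 and 0 adjusted over the list alone, adjusted p = 6.04e-07), interferon genes (12 of 28 negative, 2 positive, with 13 and 2 adjusted over the list alone, adjusted p = 0.00101) and unfolded protein response genes (7 of 20 negative, 0 positive, with 9 and 0 adjusted over the list alone, adjusted p = 0.00135) were called downward. Txnip, a glucose-responsive FOXO-list gene, rose in DKO (0.56), stood at -0.01 in TKO without a call, and had an interaction of -0.58.

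These 8 lists held with an estimated correlation. Another 6 did not. Glycolysis had 10 of 21 positive and 0 negative (adjusted p = 0.000489, and adjusted p = 0.0606 with an estimated correlation), with Ldha and Tpi1 at 0.50 and 0.52. Pentose phosphate and nucleotide synthesis had 11 of 19 positive and 2 negative (adjusted p = 0.000713, and adjusted p = 0.12 with an estimated correlation). Cholesterol genes had 10 of 24 negative and 0 positive (adjusted p = 0.00188, and adjusted p = 0.055 with an estimated correlation), and NRF2 targets had 5 of 16 negative and 0 positive (adjusted p = 0.0242, and adjusted p = 0.0606 with an estimated correlation), all of these 4 with the same counts adjusted over the list alone. BCL-2 family genes had 3 of 13 negative and 2 positive (6 and 2 adjusted over the list alone, adjusted p = 0.0314, and adjusted p = 0.311 with an estimated correlation), a call that ended without replicate 2 of TKO in low glucose (adjusted p = 0.0509), without replicate 3 of TKO in regular medium (adjusted p = 0.0668), and without Mcl1, Bax and Bak1 (adjusted p = 0.075). Early B-cell genes had 9 of 30 negative and 4 positive (12 and 4 adjusted over the list alone, adjusted p = 0.0194, and adjusted p = 0.124 with an estimated correlation). Mitochondrial fatty acid oxidation was not called, with 8 of 27 positive and 0 negative (9 positive and 1 negative adjusted over the list alone, median 0.12, adjusted p = 0.175), the acyl-CoA synthetase genes Acsl5 and Acsl3 at 0.44 and 0.66.

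**Figure D5:**
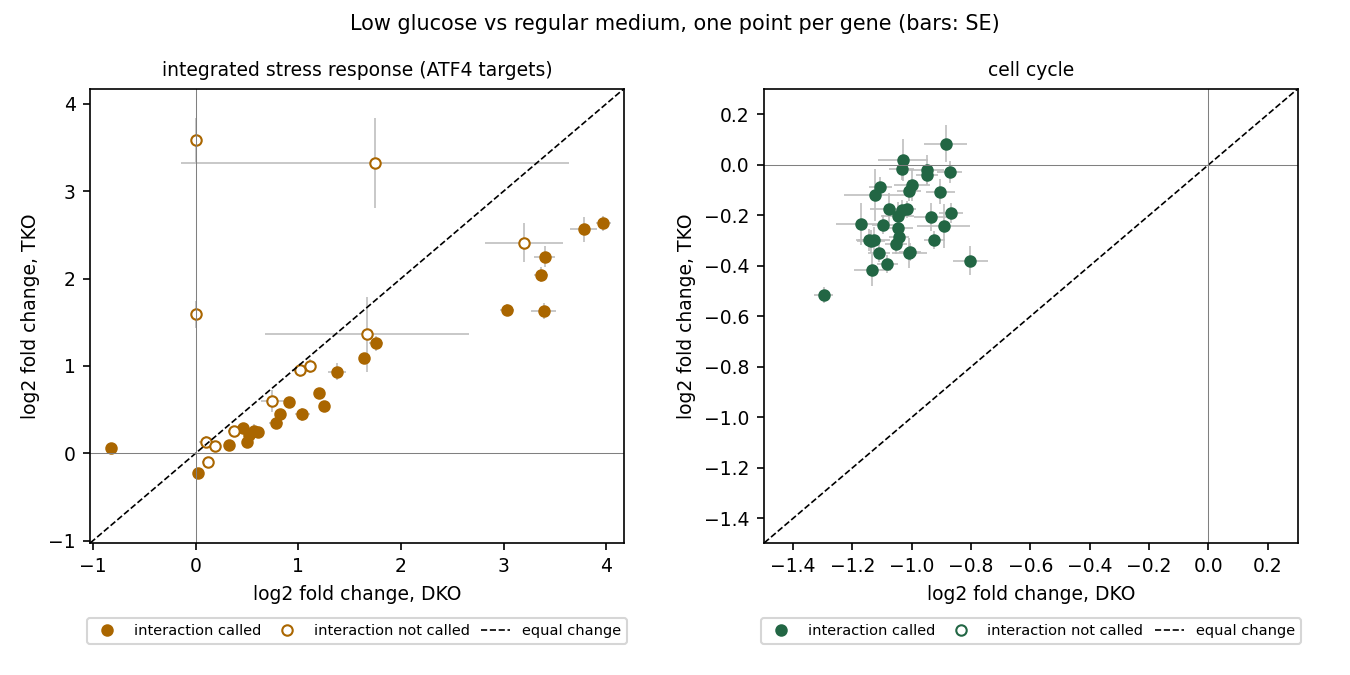
Log2 fold change in low glucose in DKO (x axis) and TKO (y axis) for each ATF4 target and each cell cycle gene, with SE bars and the line of equal change. All 34 cell cycle genes lie above the line, and 22 of 35 ATF4 targets lie below it with a called interaction.

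By that rule for the interaction, called with a mean of at least 5 CPM over all libraries, the largest positive interactions were those of Lrp4 (2.16 ± 0.348), the metallothionein gene Mt2 (1.67 ± 0.217), Elfn1 (1.62 ± 0.30) and Tnni2 (1.28 ± 0.231), and the largest negative ones those of Crisp3 (-2.62 ± 0.245), Susd3 (-1.97 ± 0.184), Glipr1 (-1.81 ± 0.247) and Cth (-1.76 ± 0.151). The call of Lrp4 ended in limma on log2(TPM + 1). Of the 519 genes that rose at least 2-fold in DKO (median log2 1.34), 348 were also called up in TKO (median 0.78), and 215 had a called negative interaction against 6 with a positive one. Of the 173 that fell at least 2-fold in DKO (median -1.13), 93 were called down in TKO (median -0.33) and 110 had a called positive interaction. Genes picked for a large change in DKO tend to change less in any second sample, so these shares lean toward a smaller change in TKO. The 317 genes that rose at least 2-fold in TKO had a median of 1.43 there and 1.05 in DKO. In all, 3553 genes had a called interaction, 2106 positive and 1447 negative (928 negative without replicate 2 of DKO in low glucose). The majority turned in other settings, with 1564 positive and 1868 negative with library size alone, and 1449 and 1991 with no filter. Across 11988 genes the 2 responses had a Pearson r of 0.548, and 1979 genes rose in both lines (831.9 for independent lists), 1733 fell in both (667.4) and 151 went opposite ways. The 2 comparisons share no library, and genes are not independent replicates.

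Of the genes in the authors' deposited tables, 7438 passed an adjusted p of 0.05 for TKO against DKO in regular medium and 8563 in low glucose. Of the genes called here 6918 and 8264 were also called there, all with the same sign, and the log2 fold changes correlated across genes at r = 0.9988 and r = 0.9992. These tables come from the same libraries and are a check of processing.

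Of 14 T-cell marker genes 3 were tested, and 3 stood above 5 CPM in DKO, which is 21.4% of the list, with Cd2 at 144 CPM and Cd28 at 17.3 CPM. In TKO 1 did, Cd2 at 211 CPM. Of the myeloid, erythroid or megakaryocytic, and stromal markers 0 stood above 5 CPM in either line, the highest being Lyz2 at 3.09 CPM in DKO. Of 30 early B-cell genes 27 stood above 5 CPM in DKO and 30 in TKO. The 13 mitochondrially encoded transcripts have no row in the count table and were not analysed here.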

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

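The criteria by which the 2 ATF4 tests on scaling and on the TKO libraries numbered 2 are read, and the values set beside them for all 35 targets and for low glucose, were chosen only after their results were seen, and the other tests in this part were not.

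The 3553 genes with a called interaction stood out because the response to low glucose differed between the lines by a test of the difference itself. Among named genes, with a mean of at least 5 CPM over all libraries, the 4 largest differences each way were these. The TKO response exceeded the DKO response by 2.16 on the log2 scale for Lrp4, 1.67 for Mt2, 1.62 for Elfn1 and 1.28 for Tnni2. The difference, TKO minus DKO, was -2.62 for Crisp3, -1.97 for Susd3, -1.81 for Glipr1 and -1.76 for Cth. Of these Lrp4 lies near the floor, at 0.145 ± 0.0786 CPM in TKO in regular medium and 0.632 ± 0.131 CPM in low glucose. Over the 3 libraries of its lowest group Lrp4 held 12 counts, Elfn1 33, Glipr1 47 and Tnni2 77. Crisp3, Susd3, Mt2 and Cth held at least 165.

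Among the gene lists, 8 differed in their response by camera with the preset and with an estimated correlation. Their median differences, TKO minus DKO, were 0.84 for the cell cycle, 0.36 for MYC and ribosome biogenesis and 0.18 for the TCA cycle. They were -0.32 for ATF4 targets, -0.33 for lysosome and autophagy, -0.34 for FOXO and glucose-sensing genes, -0.22 for the interferon response and -0.15 for the unfolded protein response.

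The medium labels were regrouped within each line 99 times at random, and with the real grouping 8 of 100 gave as many interaction genes as the real 3553, the highest of the others 5836. This test does not exclude chance and cannot decide on it. Keeping the DKO media apart while mixing the TKO media makes an interaction by itself. The 7 others were all among the 10 that kept the DKO media apart and mixed the TKO media, which gave 2644 to 5836 genes, so these counts follow a structure of the samples, the DKO response itself. The 11 that kept the TKO media apart and mixed the DKO media gave 3 to 34 genes. The 78 that mixed both gave 0 genes in edgeR, with at most 978 at an unadjusted p under 0.05.

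For each pairwise comparison 1 of the 10 splits of its 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. For TKO against DKO the real counts were 7395 in regular medium and 8941 in low glucose, and the highest other split called 0 genes in edgeR (345 and 373 at an unadjusted p under 0.05). For low glucose in DKO the real count was 7512 and the highest other 0 (111 unadjusted). For low glucose in TKO the real count was 4781 and the highest other 1044 (3142 at an unadjusted p under 0.05, against 5768 for the real split).

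Over all 35 ATF4 targets the median response was 0.60 in TKO and 0.91 in DKO and the median interaction -0.32, and the 22 with a called negative interaction, picked for it and so leaning to a larger shortfall, had medians of 0.56, 1.12 and -0.47. A higher starting level in TKO would need these genes to stand higher there in regular medium by about the shortfall. Their median there was 0.08 (quartiles -0.07 and 0.33), with 7 called higher. In low glucose 19 of the 22 were called lower in TKO (median -0.35). The pick for a negative interaction favours such genes, so that count cannot decide the question. Over all 35 the quartiles in low glucose, -0.72 and 0.17, span 0, so a part of the starting level stays open. Without both TKO libraries numbered 2 the shortfall did not shrink (-0.53, and -0.37 for all 35), which argues against these libraries as its cause. It did not shrink under other scalings either (-0.49 with DESeq2's size factors and -0.53 with library size alone, -0.34 and -0.38 for all 35). Those scalings also shifted the interactions of all genes down (median shifts of -0.023 and -0.058). A larger shortfall was thus built in, and its growth cannot test scaling. The shifts were small beside the shortfall. The bound written beforehand for these 2 tests, a move of under 10% of its size, was not met by -0.53, and the reading given here was set afterwards. Over all genes the TKO response had a slope of 0.458 on the DKO response, with a Pearson r of 0.548. A weak correlation lowers such a slope by itself, so the slope cannot show a smaller response in TKO. Medians in DKO and TKO were -1.03 and -0.22 for the cell cycle and 0.601 and 0.195 for FOXO and glucose-sensing genes. HIF targets (0.43 and 0.60) and glycolysis genes (0.05 and 0.41) went the other way. A smaller response in general thus cannot be told apart from a weaker stress response in TKO. Both may stay as hypotheses beside the starting level, with deletion of Mcl1 and any other difference between the lines untested apart.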

How the results depend on the processing

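The alternatives without Rn45s, without both TKO libraries numbered 2, and without Mcl1, Bax and Bak1 in the BCL-2 list were chosen only after the results were seen. Requiring a change of at least 2-fold left 2130 genes for TKO against DKO in regular medium, 2447 in low glucose, 692 for low glucose in DKO, 349 for low glucose in TKO and 183 for the interaction, as a stricter threshold must. All other settings kept each of the 5 counts within 1.5 times its main value, and of the genes called in both fits 1 changed sign, for the interaction in limma on log2(TPM + 1), and 0 in the other settings and comparisons. Without 1 library at a time the counts ran from 6750 to 7867, 8484 to 9204, 6846 to 7916, 3920 to 5065 and 2819 to 4079, in the same order. Without both TKO libraries numbered 2 they were 8003, 9406, 8394, 5506 and 4723. With the compared groups alone the pairwise counts were 7413, 8536, 8711 and 3298, so the gap between DKO and TKO in low glucose widened. The main fit pools the spread of both lines, and TKO libraries deviated further than DKO libraries. The balance of rises and falls moved with the setting, the 2-fold threshold left aside. The share of called genes with a positive interaction was 59.3%, and it was 42.1% with no filter, 45.6% with library size alone, 49.1% without Rn45s, 67.7% without the 20 most abundant genes and 68.8% without replicate 1 or without replicate 2 of DKO in low glucose. Negative interactions numbered 1447, and 928 without that replicate 2. For low glucose in TKO the share that rose was 55.1%, and it ran from 48.1% with no filter to 65.1% with library size alone, and the rises went from 2632 to 1743 with the compared groups alone. For low glucose in DKO it was 50.4%, and 62.7% with library size alone. For TKO against DKO it was 45.9% in regular medium and 49.9% in low glucose, with up to 54.6% (no filter) and 55.7% (limma on log2(TPM + 1)). The share of rises largely followed the shift of the median of all genes against the main fit. For the interaction that shift was -0.073 with no filter, -0.058 with library size alone and -0.043 without Rn45s. It was 0.032 without the 20 most abundant genes. The largest shift, 0.095 (log2) for low glucose in DKO with library size alone, exceeded the median SE there (0.066). The balance thus depended on where the scaling and the gene set put 0. Of 110 list tests 53 were called, 33 with an estimated correlation and 98 with fry, which asks another question. Early B-cell genes for low glucose in TKO (6 of 30 up, 13 down, adjusted p = 0.0527 by camera) gained a call in several settings. Their adjusted p was 0.0389 without Rn45s and 0.02 without replicate 2 of TKO in low glucose. Fatty acid uptake, storage and lipolysis gained one for the interaction (from 0.0579 to 0.0411 without replicate 3 of TKO in low glucose). The correlation between the responses of the lines was 0.548 and moved to 0.624 with a mean of at least 1 CPM and 0.617 over genes called in either line. Both use fewer genes with low counts or without a call. Without both TKO libraries numbered 2 the correlation was 0.499. Calls of single genes were followed for the genes of the rule and all called members of the lists, with the 2-fold threshold left aside. Settings that did not test a gene were not counted for it. Of 1864 such calls 1581 held in every setting counted, 283 were lost in at least 1 and 0 reversed. Of 6 further pairs of gene and comparison without a call 3 gained one in at least 1 setting. With the depths and 3 libraries per group used here, but with few genes planted, 45.8% to 55.1% of the smallest planted changes were called. That share does not carry over to the real comparisons.

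With the replicate number as a block (replicate block) the counts were 7542, 9038, 7626, 4962 and 3763, and 53 lists were called, so no count or list call moved by over 1.5 times. Libraries with the same number deviated together only for low glucose in TKO (r = 0.065, 0.328 and 0.229), where each low-glucose library correlated best with its own number, but replicate 1 in regular medium correlated better with replicate 3 in low glucose (r = 0.144). In the other comparisons they did not, and with replicate 1 under 0.1 the numbers were not used to pair the samples.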

Other observations

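The test of chromosome 18, its criterion on neighbouring genes and the share with Y-linked genes added were chosen only after the results were seen.

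Several lists without a call still held genes that changed. Of 21 p53 targets 9 rose and 3 fell in DKO in low glucose (adjusted p = 0.133) and 11 rose and 4 fell in TKO (adjusted p = 0.0692), each with the same counts adjusted over the list alone. Cdkn1a rose 1.47-fold in DKO and 1.48-fold in TKO, and the cell cycle gene Gtse1, also on that list, was 1.72-fold and 1.15-fold lower. Of 15 peroxisomal oxidation genes 7 rose and 3 fell in DKO (adjusted p = 0.253) and 7 rose and 2 fell in TKO (adjusted p = 0.0921), also adjusted over the list alone, with Acox3 up 1.34- and 1.45-fold. Of 18 genes of fatty acid uptake and storage 12 rose and 2 fell in DKO (adjusted p = 0.159) and 5 rose and 2 fell in TKO (adjusted p = 0.555), also adjusted over the list alone, with the lysosomal lipase gene Lipa up 1.65- and 1.31-fold. In TKO Cd36 was 1.34-fold lower in low glucose, and its interaction was -0.89 ± 0.105.

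Between the lines in regular medium, the TCA cycle (7 of 26 higher in TKO, 8 lower, adjusted p = 0.765), mitochondrial dynamics (6 of 23 higher, 9 lower, adjusted p = 0.947), pentose phosphate (3 of 19 higher, 5 lower, adjusted p = 0.947), HIF targets (5 of 18 higher, 7 lower, adjusted p = 0.93) and FOXO targets (6 of 18 higher, 7 lower, adjusted p = 0.426) were not called, each with the same counts adjusted over the list alone. Respiratory chain genes (8 of 54 higher, 10 lower, with 7 and 10 adjusted over the list alone, adjusted p = 0.63) and NRF2 targets (6 of 16 higher, 5 lower, with 7 and 5 adjusted over the list alone, adjusted p = 0.63) were not called either. Suclg2, a succinyl-CoA ligase subunit gene, was 2.12-fold higher in TKO, Bnip3 3.85-fold higher and Chchd3 1.49-fold lower.

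Genes detected in 1 line and at the floor in the other numbered 76, 35 in DKO and 41 in TKO, by at least 5 CPM in each library of 1 line and at most 3 counts in each library of the other. Gain or loss of whole chromosomes was predicted to place them on chromosomes that shifted as a whole. Of them 1.32% lay on the Y chromosome or chromosome 18. With the 4 Y-linked genes that the limit of 3 counts left out (4 to 10 counts in the highest TKO library) it was 6.25%. Another 74 lay on chromosomes with medians from -0.08 to 0.00 in regular medium and 1 had no position. The share cannot test chromosome content, since a shift like that of chromosome 18 (median log2 0.52) would not take a gene to the floor. Mixed or mislabelled libraries would carry Mcl1 into TKO, and the highest TKO library held 0.187% of the DKO mean over both media. Cells of another type would bring their marker genes, and at most 21.4% of a marker list stood above 5 CPM, the T-cell list in DKO, whose most abundant gene Cd2 (144 CPM in DKO, 211 CPM in TKO) is also expressed by mouse B cells. Losses of parts of chromosomes, separate histories of the lines or deletion of Mcl1 may account for these genes, and these were not tested.

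Both TKO libraries numbered 2 stood apart from most other TKO libraries, although replicate 3 in low glucose deviated as far (0.072 on the log2 scale for genes above 100 CPM, against 0.069 and 0.075). The deviation did not follow GC content across genes (Spearman rho 0.02) or transcript length (rho 0.07), although by library the values were -0.06 and 0.09 for GC and 0.15 and -0.02 for length. Lower depth would leave abundant genes alike, and above 100 CPM the deviation was 1.61 times that of the other 4 TKO libraries. No biological explanation was tested, since the labels give the replicates no other property.

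Chromosome 18 genes stood 1.43-fold higher in TKO at the median in regular medium and 1.52-fold higher in low glucose, 87.4% of the 238 genes lay above 0, and 198 were called higher against 22 lower in regular medium. If the TKO line had gained the whole chromosome, genes along its whole length would be raised. In 8 runs of neighbouring genes the lowest median was 0.36 and the highest 0.60 (log2). A gain of the whole chromosome may thus account for the shift, as a hypothesis from transcripts alone. The lines are compared only with each other, so a gain in TKO cannot be told apart from a loss in DKO. Y-linked genes pointed to a further difference in chromosome content, with Ddx3y at 152 ± 3.82 CPM in DKO and 0.183 ± 0.072 CPM in TKO in regular medium, and whether the Y chromosome was lost or never present was not tested.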
